A study of Rattus norvegicus with 11 samples.

How the data were processed

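Renal cortex RNA of 11 rat samples was amplified, labelled with 1 dye and hybridised to Rat 4 x 44K oligonucleotide arrays, 1 array per sample. Per the file headers, the signal intensity of each spot was extracted by the authors with Agilent Feature Extraction 11.0.1.1, which subtracts the background and evens out trends across the array, with no scaling between arrays. The deposited table of processed values holds log2 values that share 1 distribution in all columns, and the tools that made it are not given in the sources used here. Its column medians were all 7.07, and its columns correlated with the log2 scanner values at 0.9887 to 0.9969, so its scale was taken as log2 with quantile scaling, and it served as an alternative.

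Log2 of the processed signal minus the 75th percentile of each array was analysed. Of 44254 spots, 1377 control spots were left out, spots that the extraction software marked as outliers were not used unless all spots of the probe on that array were marked, and spots of 1 probe were averaged, which left 30367 probes. Of these, 18005 carried 1 gene symbol and 12362 none here, and the latter were tested and counted but not named. Probes well above background on at least 2 arrays were kept. For a gene with several such probes, the one with the highest mean signal stood for it. This gave 25249 genes, 14339 of them named.

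Replicates were checked before the fit by the spread of the log2 difference between 2 arrays, set against the spread of repeated spots within an array. DM+Sham 2 and 3 (0.018 against a spot noise of 0.065) and Control+RYGB 2 and 3 (0.050 against 0.074 and 0.093) differed by less than the spot noise and were averaged, leaving 9 samples and 5 residual degrees of freedom. This step follows a general rule on repeated arrays, but was applied after the values and the counts with 11 separate arrays had been seen. Control+Sham 1 and 2, with a spread of 0.10, were kept apart.

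Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, all 4 groups in 1 model), and p-values were adjusted by the method of Benjamini and Hochberg with a threshold of 0.05. All p-values for genes are from limma. The comparisons were diabetes in sham rats, RYGB in diabetic rats, RYGB in control rats, diabetes in RYGB rats, DM+RYGB against Control+Sham and the interaction. Gene lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, adjusted over 270 tests of 45 lists, with an estimated correlation and fry beside it. Of 1048 list entries 958 were measured. A gene below background on all arrays of a group got a bound, the mean of the brighter group over the mean of the dimmer one, each dim array being set to the higher of the gene's own signal and the lowest signal among probes well above background. With such genes at their bound, the medians of 77 called lists moved by at most 0.19 and none changed sign.

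Named genes were fixed by a rule: the 10 largest rises and 10 largest falls past the threshold without overlap of the groups' arrays for the first 3 comparisons, the same without that condition for the interaction, 5 each for the other 2, up to 4 members of each list with the smallest p, and a short fixed set that held Pgd, Me1, Idh1, Prkaa1 and Prkaa2. Pgd had no probe with its symbol here, and the texts do not name every gene of this rule. Further list members were chosen after their values were seen, as examples of a group, and so were the names without DM+RYGB 2. The comparisons, tests, naming rule, lists and most alternative settings were set before the data were examined. The demand that a gene pass under 3 scalings, the merging of arrays, the scan-day block, the leaving out of both arrays of a pair and 5 added lists for heart, skeletal muscle, liver and urothelium were chosen after the data had been seen. Opposition was read over 2 DM+Sham samples, not 3 as planned, because of the merging.

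The alternative settings were normexp background correction with an offset of 50, median and quantile scaling, the deposited table, other probe filters and summaries, the replicate number as a block, the shared slide as a block, robust and weighted fits, only the groups compared, a 2-fold threshold and leaving out each array. Normexp used the median spot signal, since the mean signal is no column of these files. Slides were told apart by scan only, so whether arrays of different scans shared a slide is not known. A random slide block could not be fitted, as 1 scan held arrays of 2 groups and the others 1 array each. A fixed term for that scan took its place. The arrays were scanned on 5 days. No day held both groups for RYGB in control rats or for DM+RYGB against Control+Sham. All Control+RYGB arrays shared a position on the slide that no other array had, so comparisons with this group cannot tell it apart from position. With scan day as a block, DM+Sham 2 and 3 entered as separate samples and 2 residual degrees of freedom were left. Days 1 to 3 were linked to days 4 and 5 by DM+Sham alone. DM+Sham 1 and 2 were scanned on days 2 and 3, and DM+Sham 3, near-identical to DM+Sham 2, on day 4. If DM+Sham 3 is DM+Sham 2 measured again, this link allows for the scan alone and not for a batch of processing.

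The fit was tested on simulated data with 200 changed genes. It recovered 83.3% of changes of 2 log2 units for diabetes in sham rats, 61.5% for RYGB in diabetic rats, 80.3% for RYGB in control rats and 44.4% for the interaction, and 24.2%, 15.3%, 34.2% and 0% of changes of 1 log2 unit, with 1 to 5 false calls. With the adjustment used, recovery and false calls depend on the share of genes changed. Far more genes passed in the real comparisons, so these figures do not carry over to them.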

Results

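Messenger RNA of the renal cortex of Sprague Dawley rats was measured on 11 single-colour oligonucleotide arrays, each of which carries probes for most rat genes. The rats were controls or had type 1 diabetes (DM) induced with streptozotocin, a toxin of the insulin-producing beta cells. After 4 weeks they underwent a sham operation or Roux-en-Y gastric bypass (RYGB), an operation that leads food past most of the stomach and the upper small intestine. The cortex was collected 4 weeks after surgery. There were 3 arrays each of Control+Sham, DM+Sham and Control+RYGB, and 2 of DM+RYGB. The labels do not say that the replicates of a group are separate animals, so the p-values may reflect technical spread. DM+Sham 2 and 3 differed by less than the spot noise and were counted as 1 sample, and so were Control+RYGB 2 and 3, which left 3 Control+Sham samples and 2 in each of the other groups.

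Between 77.7% (Control+Sham 2) and 93.5% (Control+RYGB 1) of the 30367 probes lay well above background, and none was saturated on any array. The 75th percentile of the signal ran from 1541 in Control+Sham 2 to 4454 in Control+Sham 3. Pairs of arrays within a group differed by a spread of 0.018 to 0.19 on the log2 scale, except for the 2 DM+RYGB arrays, which differed by 0.38, and pairs from different groups by 0.36 to 0.73. The number of arrays limits the precision of every value below.

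**Figure D1:**
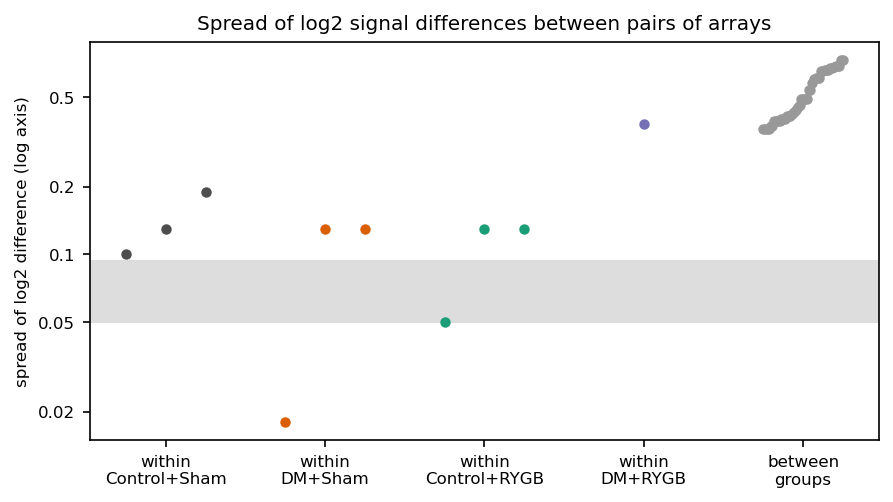
Spread of the log2 signal difference between 2 arrays (vertical axis, log scale), 1 point per pair, for pairs within each of the 4 groups and for pairs from different groups; the grey band is the range of spot noise within the arrays. The pair DM+Sham 2 and 3 lies lowest at 0.018 and the DM+RYGB pair at 0.38 lies among the pairs from different groups, which start at 0.36.

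The title of the series names NADPH synthesis, AMPK activity and diabetic nephropathy, so each comparison was read for enzymes that make NADPH and for AMPK, for 46 gene lists fixed before the data were examined, and for the genes with the largest changes. Values are log2 changes with the standard error (SE) and adjusted p of limma. A gene is said to have risen or fallen only where it passed an adjusted p of 0.05 in the same direction with the arrays scaled to their 75th percentile, to their median and by quantiles. The shift of a list is the median change of its genes minus that of all 25249 genes tested. Calls of lists rest on scaling to the 75th percentile alone. A gene below background in all arrays of a group has only a bound, written as at least N-fold.

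The lists of immediate early genes, interferon-stimulated genes, cell cycle genes and cholesterol synthesis genes shifted down with diabetes in sham-operated rats (3 Control+Sham and 2 DM+Sham samples). None of the 13 lists called in this comparison passed with an estimated correlation (adjusted p = 0.48 to 0.66). Of 25 immediate early genes, which cells switch on within minutes of a stimulus, 13 fell, 1 rose and 11 did neither. Atf3 fell by 2.32 (SE 0.10, adjusted p 7.3e-05), Egr2 fell by 2.26 and Myc fell by 2.02, whereas Jund rose by 3.67 (SE 0.16). Of 32 cell cycle genes, 18 fell and none rose, among them the cyclin Ccna2 at -1.58 and the kinase Cdk1 at -1.38. Of 30 interferon-stimulated genes, 14 fell and 2 rose, with Isg15 at -1.84 and Mx1 at -1.81. Of 22 genes of cholesterol synthesis and its control, 12 fell and none rose. Insig1, which holds the sterol sensor in the endoplasmic reticulum, fell by 1.60.

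Inflammatory genes went the same way, with 13 of 40 lower and none higher, including the chemokines Cxcl1 at -2.43 and Ccl2 at -2.03 and the cytokine Il1b at -1.31. Among 28 kidney injury genes 6 fell and 1 rose. Havcr1, which encodes the tubular injury marker KIM-1, fell by 0.63 (SE 0.10, adjusted p 0.0089), Krt20, which the urothelium also expresses, fell by 1.90 and Gadd45b fell by 2.10. A urothelium list, chosen after the values were seen, shifted by -2.79 in the same comparison (adjusted p 2.5e-08, and adjusted p = 0.49 with an estimated correlation). Among 32 fibrosis and matrix genes 7 fell and 1 rose. Fbn1 stood at -0.96 and S100a4 at -1.12, while the growth factor Tgfb2 rose by 1.60 (0.18 with a second probe). Of 18 T and B lymphocyte genes 5 fell, led by the granzyme Gzmb at -2.29. Macrophage genes fell in 2 of 20 cases, among them Adgre1 at -0.59, and genes of antigen presentation in 3 of 16, among them RT1-S3 at -0.84.

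Clock genes rose in 10 of 17 cases and fell in 3, with Tef at 1.74 (SE 0.12), Per2 at 1.36 and Nr1d2 at 1.19 against Nfil3 at -1.31. Markers of the intercalated cells of the collecting duct rose in 4 of 13 cases and none fell, among them the anion exchanger Slc4a1 at 0.92 (SE 0.23, adjusted p 0.037) and Kit at 1.07. Of 15 endothelial markers 3 rose, among them Sox18 at 1.14 and Pecam1 at 0.65.

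Among the largest single changes in diabetic sham rats, the organic anion transporter Slco1a1 fell by 9.12 (SE 0.18, adjusted p 6.6e-06), the vitamin D binding protein Gc stood at -6.17 (SE 0.21) and the trefoil peptide Tff3 at -6.54 (SE 0.21). The urothelial gene Upk2 fell by 7.01, measured above background on 1 of the 3 DM+Sham arrays, and the keratin Krt15 was at least 90.5-fold lower. Gldn stood at -7.26 (above background on 2 of 3 DM+Sham arrays) and Fgfbp1 at -6.52 (on 1 of 3), with bounds for Zp2, Or52e51 and Svs1 of at least 35.1-fold, 28-fold and 30.9-fold lower. Adtrp, a lipid esterase, rose by 5.64 (SE 0.23, adjusted p 7.3e-05), the proton pump Atp12a by 5.29 (SE 0.11) and the aryl hydrocarbon receptor target Cyp1a1 by 4.06 (SE 0.27). Kprp was at least 22.2-fold higher, Smr3b at least 17.5-fold, Senp17 at least 10.9-fold and Mbd3l1 at least 3.49-fold. Inhbc rose by 4 and Enthd1 by 4.34, both above background on 2 of 3 Control+Sham arrays, and a second probe for Enthd1 gave -0.74.

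NADPH-producing enzymes changed little as a list in diabetic sham rats. The cytosolic dehydrogenases Idh1 (-0.61, SE 0.13, adjusted p 0.021) and Me1 (-0.69, SE 0.13, adjusted p 0.018, and -1.21 with a second probe) and the mitochondrial folate enzyme Mthfd2 (-0.78, SE 0.14, adjusted p 0.015, and down to -1.27 with other probes) fell. That made 3 of 14 such enzymes lower and none higher, with a list shift of -0.06 (adjusted p 0.52). Nox4, the NADPH oxidase of tubular cells, fell by 1.88 (SE 0.20, adjusted p 0.002). The AMPK catalytic subunits Prkaa1 (-0.07, SE 0.10, adjusted p 0.67) and Prkaa2 (-0.52, SE 0.26, adjusted p 0.22) did not pass the test, though Prkaa2 did without either DM+RYGB array (adjusted p 0.0056). The AMPK-activating kinase Stk11 rose by 0.97 (SE 0.11, adjusted p 0.0028), Camkk1 rose by 0.87 (0.18 with a second probe) and the coactivator Ppargc1a rose by 0.61, while Camkk2 fell by 0.79.

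In limma's test 4173 of 25249 genes passed an adjusted p of 0.05 for diabetes in sham rats, 2261 higher and 1912 lower. With median scaling 49.7% of the calls were higher and with quantile scaling 53.4%, beside 54.2% with the 75th percentile, and the median change of all genes was 0.03. The list test camera called 13 of 45 lists, 3 up and 10 down. The shifts were -1.09 for immediate early genes (adjusted p 5.1e-09), -0.59 for interferon-stimulated genes (1.9e-08), -0.73 for the cell cycle (1.9e-08), -0.66 for cholesterol synthesis (7.6e-08), -0.67 for inflammatory genes (1.6e-06), 0.64 for intercalated cells (4e-04) and 0.86 for clock genes (0.0075), and with an estimated correlation no list passed (adjusted p = 0.48 to 0.66 for the 13 lists). Adjusted over the list alone, 18 immediate early, 20 interferon-stimulated, 22 cell cycle and 14 cholesterol genes passed. Arrays scanned on the same day gave shifts of -1.24 and -0.99 for immediate early genes, -0.79 and -0.73 for the cell cycle and -0.74 and -0.43 for cholesterol synthesis on the 2 days that held both groups. With scan day as a block 284 genes passed, and of the 13 lists only fibrosis and matrix did not (adjusted p 0.059). Leaving out 1 sample gave 1264 genes (DM+Sham 2 and 3), 1844 (Control+Sham 1), 2031 (Control+Sham 2), 2302 (DM+Sham 1), 2634 (Control+RYGB 1, or 2 and 3) and 7355 (either DM+RYGB array). Normexp left 186 genes, and array weights gave 9135 and 11 separate arrays 8265.

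**Figure D2:**
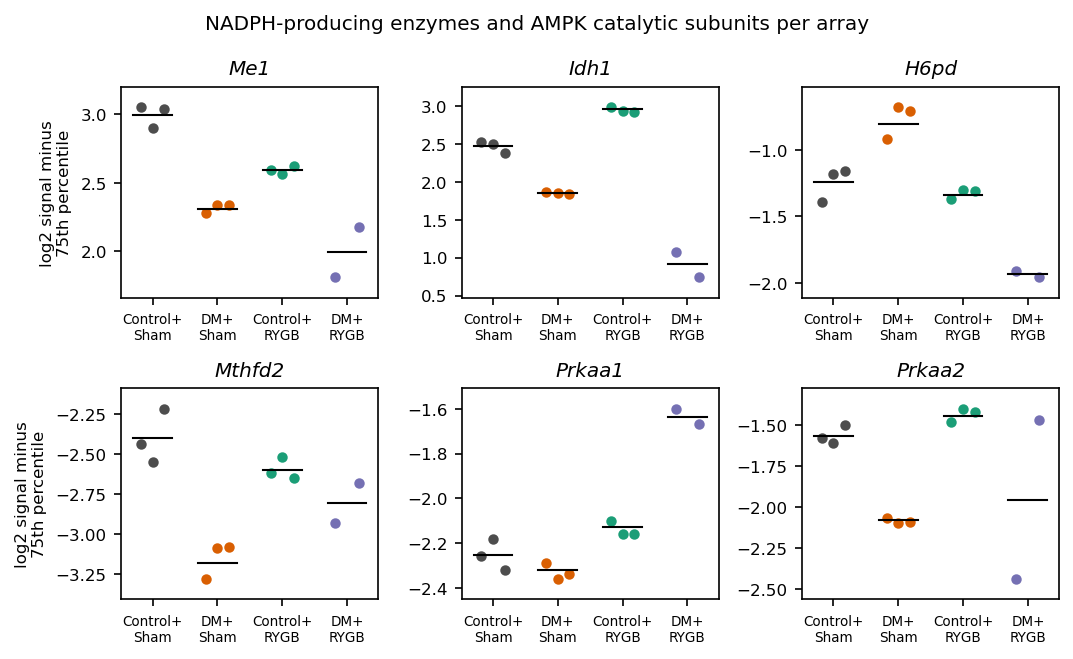
Log2 signal minus the 75th percentile of each array (vertical axes) for 4 NADPH-producing enzymes and the 2 AMPK catalytic subunits in the 4 groups; points are the 11 arrays and bars are group means over samples. Idh1 is lowest in DM+RYGB, at -1.56 against Control+Sham and Me1 is at -1 against it.

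RYGB in diabetic rats was compared with sham surgery in diabetic rats, the comparison that asks what the operation did to the diabetic kidney (2 samples against 2). The list with the smallest p was that of the proximal tubule, the segment that reabsorbs most of the filtered glucose, amino acids and bicarbonate, and none of the 14 lists called here passed with an estimated correlation (adjusted p = 0.49 to 0.72). Of 30 proximal tubule markers 18 fell, 3 rose and 9 did neither. The bicarbonate transporter Slc4a4 fell by 3.96 (SE 0.12, adjusted p 4.2e-05, and -2.5 with a second probe), the organic anion transporter Slc22a7 by 2.91 (SE 0.21) and the protein receptor Cubn by 2.35 (SE 0.18). Of 23 glucose and amino acid transporters 11 fell and none rose. The basolateral glucose transporter Slc2a2 fell by 3.70 (SE 0.21, adjusted p 0.00022), the mannose transporter Slc5a10 by 2.64 and the amino acid carriers Slc7a7 and Slc7a8 by 2.27 and 2.23.

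The lists of fatty acid oxidation and ketone metabolism shifted down as well. Some lists share members, such as Cyp2e1 in those of the proximal tubule and xenobiotic enzymes and Abcc2 in those of bile acid and antioxidant genes. Their shifts are therefore not independent. Of 42 genes of fatty acid oxidation 13 fell and 2 rose, with Vnn1 at -3.32, Angptl4 at -2.86 and the omega-hydroxylase Cyp4a1 at -2.80, whereas the fatty acid binding protein Fabp1 rose by 2.87 (SE 0.19). Of 11 ketone genes 5 fell and 2 rose. The lactate and ketone carriers Slc5a12 and Slc5a8 stood at -4.13 (SE 0.25, and -2.72 with a second probe) and -2.63 (SE 0.17). Lipid synthesis genes fell in 7 of 22 cases and rose in 1, the desaturase Fads1 at 1.69. Bile acid genes fell in 7 of 17 cases and rose in 2. The conjugating enzyme Baat fell by 3.65 and the export pump Abcb1b by 2.80 (-4.43 with a second probe), while Slco1a1, the largest fall of diabetic sham rats, rose by 5.95 (SE 0.19, adjusted p 5e-05).

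Of 38 antioxidant genes 10 fell and 4 rose. The conjugate pump Abcc2 fell by 3.18 and the plasma glutathione peroxidase Gpx3 by 2.75 (SE 0.18), while Nqo1 rose by 1.44 (SE 0.15). Xenobiotic enzymes fell in 13 of 32 cases and rose in 3, with the epoxide hydrolase Ephx2 at -2.06 and Cyp2e1 at -1.61 against Cyp2c11 at 2.61. Urea, polyamine and creatine genes fell in 8 of 23 cases and rose in 2, among them the urea cycle enzyme Ass1 at -1.74 and the polyamine enzyme Sat1 at 1.88. Glucocorticoid and insulin signalling genes fell in 6 of 27 cases, including Sgk1 at -1.67, and Igfbp2 rose by 1.24. Upward shifts were those of the distal convoluted tubule, where the calcium channel Trpv5 rose by 3.13 (SE 0.20, and 1.01 with a second probe) and the sodium-calcium exchanger Slc8a1 by 1.57, and of interferon-stimulated genes, of which 12 rose and 1 fell, with Ifit3 at 1.99 and Isg15 at 1.2. The red blood cell list shifted by -1.55 (adjusted p 0.048, and adjusted p = 0.65 with an estimated correlation) although none of its 11 genes fell or rose.

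**Figure D3:**
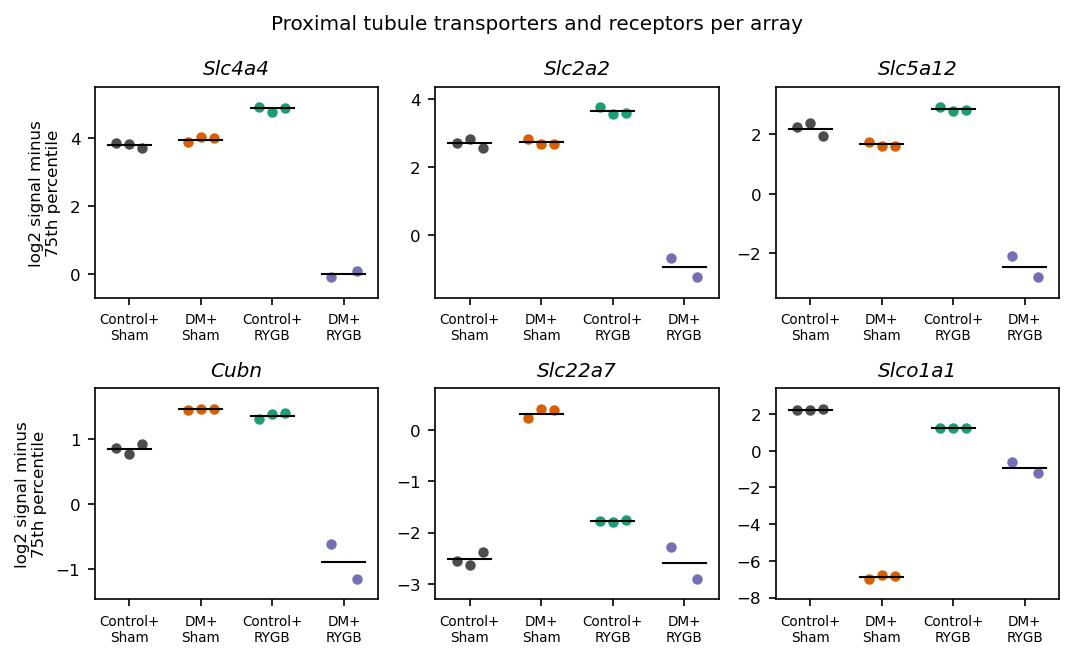
Log2 signal minus the 75th percentile of each array (vertical axes) for 6 transporters and receptors of the proximal tubule in the 4 groups; points are the 11 arrays and bars are group means over samples. Slc4a4, Slc2a2, Slc5a12 and Cubn are lowest in both DM+RYGB arrays, Slc22a7 is highest in DM+Sham, and Slco1a1 is lowest in DM+Sham, at -9.12 against Control+Sham.

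The largest falls after RYGB in diabetic rats were those of the urea transporter Slc14a2 at -7.81 (SE 0.22, above background on 1 of 2 DM+RYGB arrays, and -1.95 with a second probe), Fam111a at -5.75 (SE 0.19), the bile acid ligase Slc27a5 at -5.35 (SE 0.20), Cldn23 at -5.23, Atp12a at -4.27 and Nrn1l at -4.16. Kprp was at least 19.6-fold lower, Senp17 at least 9.61-fold and Mmp20 at least 8.54-fold, but with normexp background correction Senp17 stood at 0.65 and Mmp20 at 0.79, short of the threshold. The steroid dehydrogenase Akr1c2 rose by 6.52 (SE 0.28, adjusted p 0.00012), Zp2 was at least 20.7-fold higher and Or52e8b at least 17-fold. Of the 10 largest rises of named genes 7 belonged to muscle genes and were largest in DM+RYGB 2, in which heart muscle transcripts were far above all other arrays, but 5 of these 7 genes were above background in DM+Sham and also passed without that array. Myh6, the alpha heavy chain of cardiac myosin, stood at 8.52 (SE 2.86, adjusted p 0.042) and at 3.29 (adjusted p 0.00092) without DM+RYGB 2, and Ckm at 6.29 (SE 1.98, adjusted p 0.035) and at 2.69 (adjusted p 0.0032). Myh8 at 6.27 (above background on 2 of 3 DM+Sham arrays), Lrrc39 at 6.22 and Myom2 at 6.10 likewise passed without that array, at 2.22 to 2.85 (adjusted p 2e-04 to 0.026). Mybpc3 and Cav3 were below background in DM+Sham, with bounds of 106-fold and 60.7-fold over both DM+RYGB arrays. DM+RYGB 1, set against DM+Sham 3 of the same scan day, gave log2 differences of 3.35 and 2.61, short of these bounds. With both arrays none of these 7 passed under all 3 scalings. Without DM+RYGB 2, genes named after their values were seen included Mageb3, Mup4l3, Msln, Fcrl6, Pwwp2a and Tsg101, of which Msln stood at 5.71 with that array and at 5.96 without it.

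**Figure D4:**
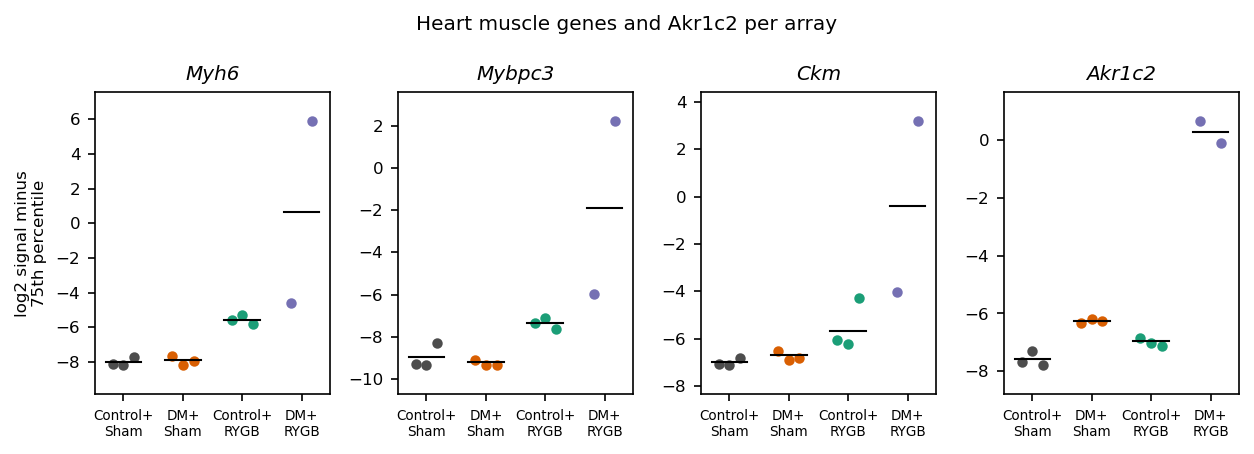
Log2 signal minus the 75th percentile of each array (vertical axes) for 3 muscle genes and Akr1c2 in the 4 groups; points are the 11 arrays and bars are group means over samples. The muscle genes separate the 2 DM+RYGB arrays from each other, and Akr1c2 is high in both, with a group mean of 0.25 against -6.27 in DM+Sham.

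Of 14 NADPH-producing enzymes 3 fell and none rose after RYGB in diabetic rats. Their median change was -0.2, which is a list shift of -0.76 relative to all genes (adjusted p 0.035) that did not pass (adjusted p = 0.49) with an estimated correlation. H6pd, the enzyme that makes NADPH inside the endoplasmic reticulum, fell by 1.13 (SE 0.13, adjusted p 0.0013, and -0.34 with a second probe) and Idh1 by 0.94 (SE 0.14, adjusted p 0.0026). Me1 stood at -0.31 (SE 0.15, adjusted p 0.11). Aldh1l2, at 1.34, and Mthfd2l, at 0.81, were higher with the 75th percentile but did not pass under every scaling. The pentose phosphate list shifted by -0.61 (adjusted p 0.054), with 4 of 12 genes lower and none higher. Prkaa1 rose by 0.69 (SE 0.11, adjusted p 0.003), the regulatory AMPK subunits Prkag1 by 0.99 and Prkag3 by 1.66 (2.76 with a second probe), and Prkaa2 stood at 0.13 (SE 0.28, adjusted p 0.72), at -0.24 with quantile scaling, at -0.36 (adjusted p 0.025) without DM+RYGB 2 and at 0.61 (adjusted p 0.0059) without DM+RYGB 1. AMPK subunits and regulators as a list shifted by -0.45 (adjusted p 0.31), with 3 of 28 higher and 4 lower.

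For RYGB in diabetic rats 13342 genes passed in limma, 10580 higher and 2762 lower. The share of higher calls was 79.3% with the 75th percentile, 57.9% with median scaling and 38.6% with quantile scaling, and the median change of all genes moved from 0.57 to 0.25 and -0.06, so the balance of directions depends on the scaling. With all 3 scalings 3304 genes were higher and 2760 lower. Camera called 14 lists, 2 up and 12 down, with shifts of -1.51 for the proximal tubule (adjusted p 2.4e-09), -0.96 for glucose and amino acid transporters (2.7e-07), -0.68 for fatty acid oxidation (3.6e-06), -0.83 for xenobiotic enzymes (0.00023), -1.25 for ketone genes (0.0054), 0.80 for the distal convoluted tubule (0.038) and 0.29 for interferon-stimulated genes (0.034), with adjusted p = 0.49 to 0.72 for the 14 lists with an estimated correlation. Adjusted over the list alone, 22 proximal tubule genes, 13 transporters and 16 fatty acid genes passed. The 1 scan day that held both groups, with 1 array of each, gave -1.29, -1.11 and -1 for these 3 lists. With scan day as a block their shifts were -1.38, -1.16 and -0.77 and 4937 genes passed, while of the 14 lists interferon-stimulated genes alone did not (adjusted p 0.13). The DM+Sham array of the shared day was DM+Sham 3, near-identical to DM+Sham 2 of another day. If it is that array measured again, both results allow for the scan alone and not for a batch of processing. Leaving out both DM+Sham arrays counted as 1 sample left 7873 genes, normexp 5409, array weights 7217 and a fit of only the groups compared 6221.

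RYGB in control rats was compared with sham surgery in control rats, which asks what the operation did to a kidney without diabetes (2 samples against 3). None of the 9 lists called here passed with an estimated correlation (adjusted p = 0.48 to 0.75). Interferon-stimulated genes fell in 13 of 30 cases and rose in 1, with Irf7 at -1.58 (SE 0.09), Isg15 at -1.21 and Mx1 at -1.1 against Irf1 at 1.21. Cholesterol genes fell in 8 of 22 cases and cell cycle genes fell in 5 of 32, among them Mcm3 at -0.75. Markers of smooth muscle and mesangial cells fell in 5 of 16 cases, including the smooth muscle myosin Myh11 at -1.13 (-0.77 with a second probe). Matrix genes fell in 8 of 32 cases and rose in 2, with S100a4 at -1.71 and Tgfb2 at 2.08 (0.86 with a second probe). Of 13 principal cell markers 3 fell, among them the water channel Aqp4 at -1.95 (SE 0.28) and Elf5 at -2.30, for which a second probe gave 1.25. Of 23 genes in the list of urea, polyamine, creatine and ammonia metabolism, which also holds other amino acid enzymes, 7 rose and 1 fell. Cps1, which starts the urea cycle, rose by 2.12 (SE 0.21, above background on 1 of 3 Control+Sham arrays), and Tat, which degrades tyrosine, was at least 12.6-fold higher. A liver list, chosen after the values were seen, shifted in the same direction, by 1.33 (adjusted p 9.2e-05, and adjusted p = 0.58 with an estimated correlation). Of 30 proximal tubule markers 2 rose and none fell, among them Cyp2e1 at 1.1. Lipid synthesis genes fell in 2 of 22 cases, among them Fasn at -0.77, and rose in 1, Scd at 1.59.

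The largest rises after RYGB in control rats were those of the neuropeptide Gal at 7.23 (SE 0.57, adjusted p 0.00099), Adtrp at 6.32 (SE 0.23), Cyp3a2 at 5.36 (SE 0.15), Jund at 4.45 (SE 0.16) and the prekallikrein gene Klkb1 at 4.32. Klkb1, Mup4l3 at 5.40, Lcn5 at 5.38, Spetex2g at 5.37 and Mup4 at 4.52 were above background on 1 of 3 Control+Sham arrays. The largest falls were those of Slc14a2 at -8.65 (SE 0.20, adjusted p 1.9e-05, and -5.96 with a second probe), Gldn at -6.17, Krt15 at -5.59 (above background on 1 of 3 Control+RYGB arrays), Upk2 at -5.55 and Rab9b at -5.02 (on 2 of 3, and -1.68 with a second probe). Fgfbp1 was at least 71.7-fold lower, Svs1 at least 30-fold, Or52e51 at least 27.3-fold, Anxa8 at least 20.7-fold and Mmp20 at least 8.89-fold. Of these, Upk2, Krt15, Gldn, Fgfbp1, Svs1 and Or52e51 had also fallen in diabetic sham rats, but both comparisons use the same Control+Sham samples and are not independent.

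Me1 (-0.41, SE 0.13, adjusted p 0.061, and -0.62 with a second probe), Prkaa1 (0.12, SE 0.10, adjusted p 0.36) and Prkaa2 (0.12, SE 0.26, adjusted p 0.76) did not pass for RYGB in control rats. Idh1 stood at 0.49 (SE 0.13, adjusted p 0.033) but did not pass under every scaling. NADPH-producing enzymes shifted by -0.34 (adjusted p 0.21) and AMPK subunits and regulators by -0.26 (adjusted p 0.28).

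In limma 6843 genes passed for RYGB in control rats, 5453 higher and 1390 lower. The share of higher calls was 79.7% with the 75th percentile, 66.4% with median scaling and 40.2% with quantile scaling, the median change of all genes was 0.29, 0.16 and -0.04, and with all 3 scalings 1962 genes were higher and 1387 lower. Camera called 9 lists, 2 up and 7 down, among them interferon-stimulated genes (-0.67, adjusted p 2e-07), cholesterol synthesis (-0.47, 7.2e-05), the cell cycle (-0.45, 7.2e-05), proximal tubule markers (0.33, 0.0074) and urea metabolism (0.44, 0.025), with adjusted p = 0.48 to 0.75 for the 9 lists with an estimated correlation. Adjusted over the list alone, 15 interferon-stimulated and 13 cholesterol genes passed. No scan day held both groups, and with scan day as a block limma called 0 genes, with 4185 at an unadjusted p under 0.05, and of the 9 lists only lipid synthesis did not pass (adjusted p 0.056). The 2 groups also lay at different positions on the slide throughout, which this block does not allow for. Leaving out 1 sample gave 742 genes (Control+RYGB 1), 965 (Control+RYGB 2 and 3), 2107 (Control+Sham 1) and 2542 (Control+Sham 2). Normexp left 105 genes, and array weights gave 16104 and 11 separate arrays 11716.

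Diabetes in RYGB rats, which asks how the diabetic and the control kidney differed once both had been operated on (2 samples against 2), gave the most list shifts, 22 of 45, with 5 up and 17 down, none of which passed with an estimated correlation (adjusted p = 0.48 to 0.75). Proximal tubule markers fell in 21 of 30 cases and none rose, with Slc4a4 at -4.87 (SE 0.12, adjusted p 4e-05, and -3.22 with a second probe), Cubn at -2.24 and the water channel Aqp1 at -1.70. The list of urea, polyamine, creatine and ammonia metabolism, which also holds other amino acid enzymes, had 12 of 23 genes lower. Among them were Gatm, which makes the creatine precursor, at -1.76 and the amino acid decarboxylase Ddc at -2.81. The liver list also shifted down, by -2.01 (adjusted p 7.3e-13, and adjusted p = 0.49 with an estimated correlation). Transporters of glucose and amino acids fell in 13 of 23 cases, with Slc2a2 at -4.61 (SE 0.21) and the neutral amino acid transporter Slc6a19 at -3.01. Immediate early genes fell in 14 of 25 cases, including Egr2 at -4 and Jund at -3.58, and the chemokine Cxcl10 at -4.46 (SE 0.14) led 13 of 40 inflammatory genes that fell. Havcr1 fell by 2.51 (SE 0.11, adjusted p 9.7e-05) among 8 of 28 kidney injury genes. Lists of distal segments, podocytes and the endothelium shifted up. Intercalated cell markers rose in 10 of 13 cases, with the chloride-bicarbonate exchanger Slc26a4 at 1.95 (SE 0.17), principal cell markers in 7 of 13, with the sodium channel subunit Scnn1g at 1.83, and distal convoluted tubule markers in 5 of 9, with Slc12a3 at 1.29. Podocyte markers rose in 8 of 18 cases, with nephrin, Nphs1, at 1.5 (SE 0.19), and endothelial markers in 5 of 15, with Cldn5 at 2.29. Among clock genes, whose list was not called here, Bmal1 stood at -4.23 and -3.93 with 2 probes and Dbp at 3.23 to 4.2 with 3 probes. After RYGB in diabetic rats Bmal1 stood at -2.92 and -2.19 and Dbp at 1.61 to 2.65. Such opposite changes cancel in a list shift.

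Idh1 fell by 2.04 (SE 0.14, adjusted p 0.00031) in diabetic against control RYGB rats and H6pd fell by 0.60 (SE 0.13, and -0.19 with a second probe). Nox4 fell by 2.99 and the oxidase subunit Cyba by 1.45. Me1 stood at -0.59 (SE 0.15, adjusted p 0.024, not under every scaling) and Prkaa2 at -0.51 (SE 0.28, adjusted p 0.22), at -1 (adjusted p 0.0014) without DM+RYGB 2 and at -0.03 (adjusted p 0.86) without DM+RYGB 1. Prkaa1 stood at 0.50 (SE 0.11, adjusted p 0.013, not under every scaling), while Prkag1 rose by 1.02 and Prkag2 by 0.86. The pentose phosphate list shifted by -0.52 (adjusted p 0.039, and adjusted p = 0.65 with an estimated correlation) and NADPH-producing enzymes by -0.47 (adjusted p 0.059). The largest rises were Akr1c2 at 7.21 (SE 0.28), Rbfox1 at 4.82 (2.51 without DM+RYGB 2), Or52e8b at least 16.5-fold and the antimicrobial lectin Reg3b at least 16-fold, and Myom2 stood at 5.81 with and 2.56 without DM+RYGB 2. The largest falls were Acot5 at -5.53, Akr1b10 at -5.41, Fam111a at -5.37, the pentraxin Apcs at -5.37 and Slc5a12 at -5.30 (-3.53 with a second probe).

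In limma 7745 genes passed for diabetes in RYGB rats, 5067 higher and 2678 lower, and the share of higher calls was 65.4% with the 75th percentile, 42.8% with median scaling and 45.8% with quantile scaling around a median change of 0.27, 0.04 and 0.01. With all 3 scalings 2361 were higher and 2470 lower. The list shifts included -1.43 for the proximal tubule (adjusted p 1.2e-12), -1.08 for urea metabolism (5.7e-09), -1.02 for immediate early genes (2.6e-07), 0.92 for intercalated cells (0.00042), 1.17 for principal cells (0.0038) and 0.54 for podocytes (0.037), with adjusted p = 0.48 to 0.75 for the 22 lists with an estimated correlation. The 2 scan days that held both groups gave -1.25 and -1.63 for the proximal tubule and 1.2 and 0.66 for intercalated cells, and with scan day as a block 3182 genes passed and of the 22 lists only podocytes did not (adjusted p 0.07). Adjusted over the list alone, 24 proximal tubule genes passed. Without Control+RYGB 1 the count of genes was 3712, and without Control+RYGB 2 and 3 it was 3554. Normexp gave 3245, array weights 4897 and a fit of only the groups compared 1692.

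Operated diabetic rats were also set against sham-operated controls, to show how far the operated diabetic kidney lay from the healthy one (2 samples against 3). None of the 19 lists called here passed with an estimated correlation (adjusted p = 0.48 to 0.75). Cholesterol genes fell in 12 of 22 cases and none rose, with Dhcr7 at -2.17. Proximal tubule markers fell in 17 of 30 cases and none rose, with Slc4a4 at -3.80 (-2.53 with a second probe). Matrix genes fell in 13 of 32 cases and rose in 3, with fibronectin, Fn1, at -1.69 (SE 0.11, and -0.56 with a second probe) and the collagen Col1a2 at -1.06 against vimentin, Vim, at 1.38. Cell cycle genes fell in 14 of 32 cases, with Cdk1 at -1.72, and Havcr1 fell by 2.02 (SE 0.10). Lipid synthesis genes fell in 8 of 22 cases and rose in 2, with Fasn at -1.90 (list shift -0.79, adjusted p 3e-04, and adjusted p = 0.56 with an estimated correlation). Intercalated cell markers rose in 9 of 13 cases, with Slc4a9 at 2.20, distal convoluted tubule markers in 5 of 9, with Trpv5 at 3.65 (1.9 with a second probe), and endothelial markers in 6 of 15.

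Of 14 NADPH-producing enzymes 6 fell and 1 rose in DM+RYGB against Control+Sham, with a list shift of -0.92 (adjusted p 0.0092, and adjusted p = 0.49 with an estimated correlation). Idh1 fell by 1.56 (SE 0.13, adjusted p 0.00033), Me1 by 1 (SE 0.13, adjusted p 0.0014, and -1.39 with a second probe) and H6pd by 0.69 (SE 0.12), for which a second probe gave 0.24, and Aldh1l2 rose by 1.49. Nox4 fell by 2.46. Prkaa1 stood at 0.62 (SE 0.10, adjusted p 0.0023, not under every scaling) and Prkaa2 at -0.39 (SE 0.26, adjusted p 0.22), at -0.88 (adjusted p 0.0013) without DM+RYGB 2 and at 0.09 (adjusted p 0.41) without DM+RYGB 1, while Prkag3 rose by 2.02 (3.1 with a second probe) and Camkk2 fell by 1.25 (0.95 with normexp, short of the threshold). Among the largest falls were Slc14a2 at -8.38 (above background on 1 of 2 DM+RYGB arrays, and -6.01 with a second probe), Acot5 at -6.99, Fgfbp1 at least 40.8-fold lower and the anion transporter Slco4a1 at -5.60. Akr1c2 rose by 7.84 (SE 0.25), and like Myh7, Myh6 and Tnni3 it was above background on 1 of 3 Control+Sham arrays. The heart genes Myh7 at 9.26 (SE 2.68), Ckmt2 at least 153-fold, Myh6 at 8.65 and Tnni3 at 8.28 were highest in DM+RYGB 2. Without it Myh7, Myh6 and Tnni3 stood at 3.96, 3.42 and 2.42. Ckmt2 was below background in Control+Sham, and its bound is taken from the mean of both DM+RYGB arrays, so it need not hold in DM+RYGB 1.

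In limma 15289 genes passed for DM+RYGB against Control+Sham, 12258 higher and 3031 lower. The share of higher calls was 80.2% with the 75th percentile, 59.1% with median scaling and 42.5% with quantile scaling, the median change of all genes was 0.59, 0.24 and -0.02, and with all 3 scalings 3815 were higher and 3026 lower. Camera called 19 lists, 3 up and 16 down, with -1.14 for cholesterol synthesis (adjusted p 1.5e-08), -1.15 for the proximal tubule (1.5e-08) and -0.84 for the matrix (0.00044), and the 19 lists had adjusted p = 0.48 to 0.75 with an estimated correlation. Adjusted over the list alone, 16 cholesterol, 20 proximal tubule and 22 matrix genes passed. No scan day held both groups, and with scan day as a block limma called 0 genes, with 8504 at an unadjusted p under 0.05, and of the 19 lists antioxidant genes (adjusted p 0.095) and endothelial markers (adjusted p 0.14) did not pass. Normexp gave 7080 genes.

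The interaction asks whether RYGB acted differently in diabetic and control rats. None of the 15 lists called here passed with an estimated correlation (adjusted p = 0.49 to 0.75). Among the lists fixed beforehand, interferon-stimulated genes had the smallest p of a positive difference, with 18 of 30 more positive after RYGB in diabetic than in control rats and 1 more negative, among them Ifit3 at 2.66, Irf7 at 2.48 (SE 0.14) and Isg15 at 2.41 (adjusted p 4e-04). This list was also below Control+Sham both with diabetes and after RYGB in control rats, so high values in Control+Sham may give part of the difference. Proximal tubule markers had the smallest p of a negative one, with 18 of 30 more negative and 1 more positive, led by Slc4a4 at -5.03 (SE 0.16, adjusted p 8.6e-05, and -3.19 with a second probe) and Slc22a7 at -3.65. Fatty acid oxidation was more negative in 13 of 42 genes, with Vnn1 at -4.28 and Angptl4 at -3.69, and the antioxidant list in 9 of 38, with Abcc2 at -3.73 and Gpx3 at -3.71. T and B lymphocyte genes were more positive in 4 of 18 cases, among them Gzmb at 3. Idh1 had a difference of -1.43 (SE 0.19, adjusted p 0.0038) and H6pd of -1.04 (SE 0.18), whereas Me1 at 0.10 (SE 0.20, adjusted p 0.76) and Prkaa2 at 0.01 (SE 0.38, adjusted p 0.99) did not pass, and Prkaa2 stood at -0.48 (adjusted p 0.03) without DM+RYGB 2 and at 0.49 (adjusted p 0.031) without DM+RYGB 1. Prkaa1 at 0.57 (SE 0.14, adjusted p 0.033) did not pass under every scaling, and Prkag1 had a difference of 1.19 (SE 0.15).

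In limma 5588 genes passed for the interaction, 3393 positive and 2195 negative, and the positive share was 60.7% with the 75th percentile and 43.3% with median and with quantile scaling. The median of all genes was 0.23, 0.04 and -0.03, and with all 3 scalings 1912 were positive and 2039 negative. Camera called 15 lists, 5 up and 10 down, among them -1.69 for the proximal tubule (adjusted p 1.4e-10), -0.76 for fatty acid oxidation (2.9e-06) and 0.88 for interferon-stimulated genes (2.5e-05), and the 15 lists had adjusted p = 0.49 to 0.75 with an estimated correlation. Adjusted over the list alone, 23 proximal tubule, 15 fatty acid and 20 interferon-stimulated genes passed. With scan day as a block 93 genes passed, these 3 shifts were -1.72, -0.82 and 0.89, and of the 15 lists only principal cell markers did not pass (adjusted p 0.099). Leaving out 1 sample gave 2321 genes (Control+RYGB 2 and 3), 2658 (Control+RYGB 1), 2876 (DM+Sham 2 and 3), 3297 (Control+Sham 1) and 8394 (DM+RYGB 2). Normexp gave 1124 and 11 separate arrays 9517.

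Across genes, the covariance between the change after RYGB in diabetic rats and the change with diabetes, given below, was more negative than that simulated from the spread within groups. Of the genes past the threshold in both comparisons, 1857 went in opposite directions and 605 in the same one, beside 1049 and 1157 for independent lists of these sizes and 0 in a limma simulation without effects, which calls hardly any gene. Neither value allows for both the effects and the shared DM+Sham samples, from which part of the excess may come. Isg15 (-1.84, then 1.2), Ifit2 (-1.37, then 1.36) and Slco1a1 (-9.12, then 5.95) fell with diabetes and rose after RYGB, and Atp12a (5.29, then -4.27) did the reverse. Other genes were low in diabetes and did not return, such as Nox4, at -1.88 with diabetes and -2.46 in DM+RYGB. Genes higher and then lower numbered 725 (independent lists 247), those lower and then higher 1132 (801), those higher both times 409 (947) and those lower both times 196 (209). With quantile scaling these counts were 1208, 556, 79 and 391, so opposite directions still prevailed but the balance among them depended on the scaling. The DM+Sham samples enter both comparisons, which alone gives a simulated covariance across genes of -0.0753. The simulation draws its noise from the spread within groups, so it lacks any deviation that all DM+Sham arrays share. Reading 1 DM+Sham sample against the other does not remove such a deviation either, so neither can tell it from an opposition of effects. The observed covariance was -0.314, a difference of -0.24 that shrank to -0.04 with normexp, -0.13 with the deposited table, -0.16 with probes above background on all arrays and -0.17 with quantile scaling, and was -0.15 without DM+Sham 2 and 3, -0.44 without DM+Sham 1 and -0.39 with scan day as a block. The correlation across genes, which are not independent replicates, was -0.372 beside -0.548 in the simulation. With genes called from 1 DM+Sham sample and the RYGB change read against the other, 79.8% and 84.2% of the genes higher in diabetes were below the median change, and 65.2% and 58.5% of the genes lower in diabetes were above it.

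**Figure D5:**
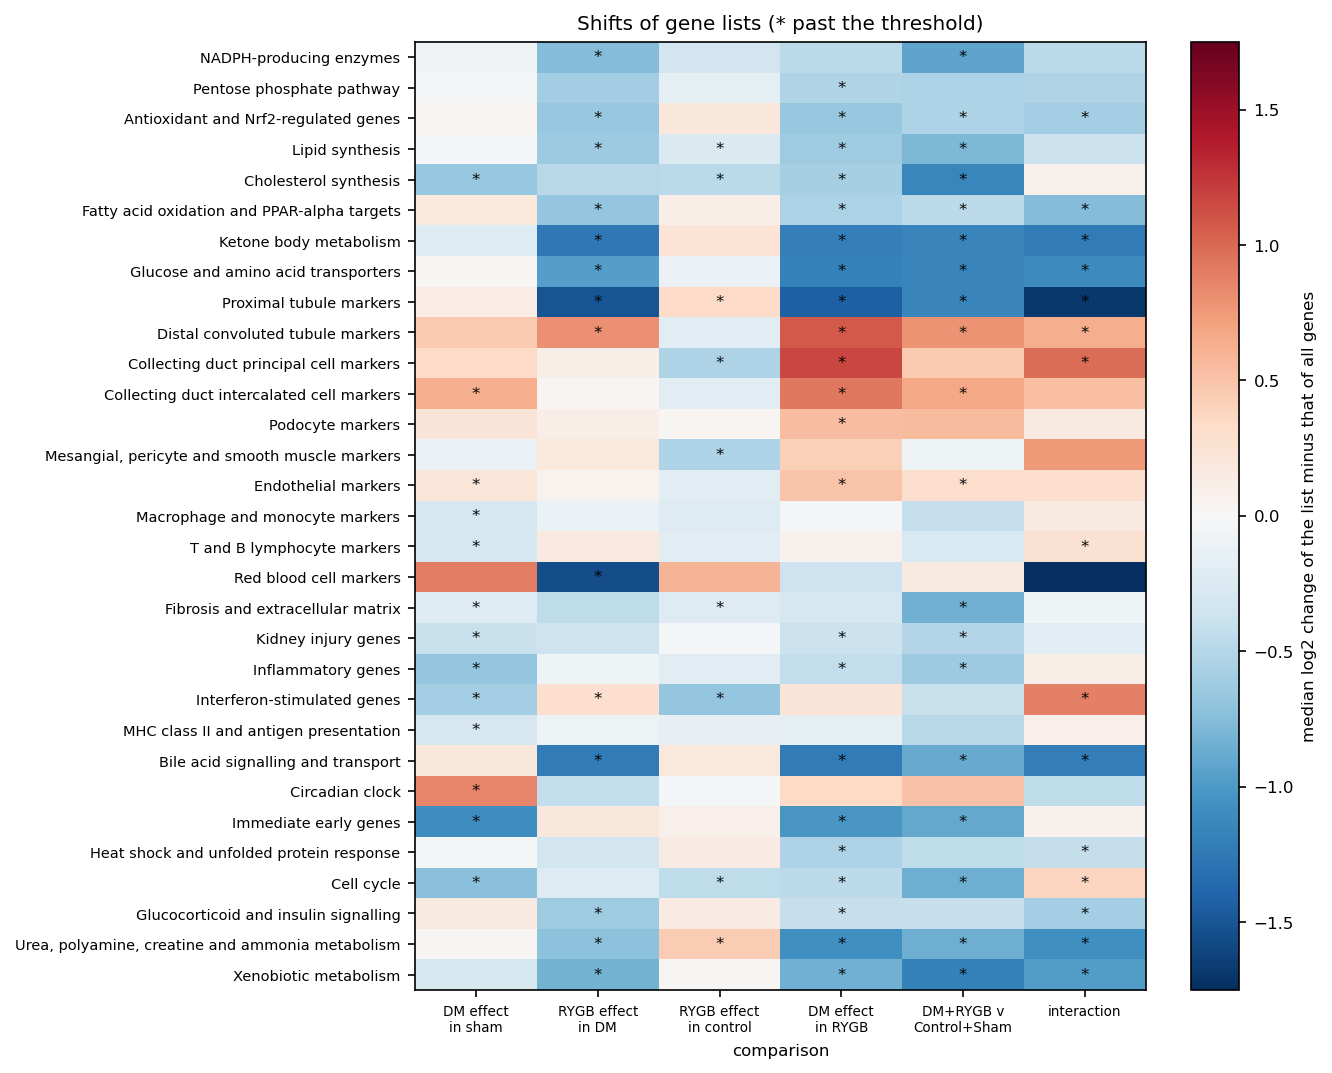
Shift of each gene list (colour, median log2 change of the list minus that of all genes) in the 6 comparisons, for lists called in at least 1 comparison; an asterisk marks an adjusted p under 0.05 in camera with the preset correlation of 0.01. Proximal tubule markers run from -1.69 in the interaction to 0.33 for RYGB in control rats.

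Over all comparisons camera called 92 of 270 list tests with its preset correlation of 0.01, 20 up and 72 down. With the correlation estimated per list it called 0, with 25 at an unadjusted p under 0.05, and the estimated p of the lists named above lay between 0.48 and 0.75. Fry, which asks whether the genes of a list move 1 way on balance without reference to other genes, called 149, including 77 of the 92. For the lists that camera called, the median shift, the mean shift and the test had the same sign. Among genes of the lists, probes of 1 gene passed in opposite directions for Aldoc with diabetes in sham rats (-0.63 and 0.75), Pfkfb3 in DM+RYGB against Control+Sham (-1.06 and 0.59), Tgfb2 after RYGB in diabetic rats (-1.88 and 1.33) and Elf5 after RYGB in control rats.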

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

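The tests of heart transcripts, near-identical arrays and proximal tubule markers were chosen after these results were seen, and the test by splits of the arrays was written after the count of the real split was known but before the other splits were counted.

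The DM effect differed between sham and RYGB rats in 5588 genes of limma's interaction test. The 20 largest differences of log2 changes passed under all 3 scalings. They were positive for the epithelial genes Krt15 at 8.87, Upk2 at 7.28 and Msln at 7.30, for Gldn at 8.56, Svs1 at 8.02, Or52e51 at 10.86, Fgfbp1 at 7.15, Pnoc at 7.18 and the muscle gene Trim55 at 7.04 (5.27 without DM+RYGB 2), and for the anion transporter Slco1a1 at 6.96. They were negative for Adtrp at -9.59, Jund at -7.25, Atp12a at -5.18, Fam111a at -5.84, Kprp at -5.73, Senp17 at -5.49 and Vom1r82 at -5.32, and for the liver-type genes Slc27a5 at -7.09, Baat at -5.20 and Serpina10 at -5.23. For genes of this set that were below background in a group these values depend on the floor and are no bounds, and with normexp Kprp, Senp17 and Vom1r82 stood at 0.24, 0.89 and 1.46, short of the threshold. Krt15, Upk2, Gldn, Svs1, Or52e51 and Fgfbp1 had fallen against Control+Sham both with diabetes and after RYGB in control rats. High values in Control+Sham alone would give such a positive difference, so it need not reflect an action of RYGB in diabetic rats. Adtrp and Jund were higher than in Control+Sham in both comparisons, so low values there may likewise give part of their negative differences.

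Among the other named genes, interferon genes differed by 2.66 (Ifit3), 2.48 (Irf7) and 2.41 (Isg15), the granzyme Gzmb by 3, and the AMPK subunits Prkag1 and Prkaa1 by 1.19 and 0.57, of which Prkaa1 did not pass under every scaling. Isg15 and Gzmb were also lower than in Control+Sham both with diabetes and after RYGB in control rats, so the same limit holds for them. Slc4a4 at -5.03, Slc22a7 at -3.65, Vnn1 at -4.28, Angptl4 at -3.69, Abcc2 at -3.73, Gpx3 at -3.71, Idh1 at -1.43 and H6pd at -1.04 were more negative after RYGB in diabetic rats.

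As lists, proximal tubule markers differed by -1.69, ketone genes by -1.22, bile acid genes by -1.21, glucose and amino acid transporters by -1.11, urea metabolism by -1.08, xenobiotic enzymes by -0.98, fatty acid oxidation by -0.76, antioxidant genes and glucocorticoid and insulin signalling by -0.6 each, and heat shock genes by -0.42. Principal cell markers differed by 0.98, interferon-stimulated genes by 0.88, distal convoluted tubule markers by 0.63, the cell cycle by 0.38 and T and B lymphocyte markers by 0.27. The interferon and cell cycle lists were below Control+Sham both with diabetes and after RYGB in control rats, so high values there may give part of their differences. None of these 15 passed with an estimated correlation (adjusted p = 0.49 to 0.75).

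DM+RYGB 2 held heart transcripts. Over 24 ventricular genes its median difference from DM+RYGB 1 was 7.68, with 20 genes over 2, beside -0.19 for all genes, and 16 of the 24 were above background on all Control+Sham arrays. Among the 11 ventricular genes not yet seen when the list was written it was 3.04, so heart RNA in that sample is a candidate explanation that the test left standing, with atrial genes at 1.73. Skeletal muscle, at a median of 0.16 over 13 genes, and an effect shared by the DM+RYGB samples in similar measure, at 0.62 in DM+RYGB 1 against 8.12 in DM+RYGB 2, were argued against. Single muscle genes such as Myh6, at 3.29 after RYGB in diabetic rats without DM+RYGB 2, were higher in DM+RYGB 1 too, which these tests leave open. No biological explanation was tested, and how heart RNA could have reached a kidney sample stays open.

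DM+Sham 2 and 3 had a spread of 0.018, and their spot noise correlated at 0.91, above the highest value of 0.51 between groups, so that 1 array measured again is a candidate explanation that fits the value. This bound does not single out such arrays, as Control+Sham 1 and 2 (0.69) and other pairs within Control+Sham (0.54) and DM+Sham (0.53) also lay above it and were kept apart by their spread. Control+RYGB 2 and 3 had a spread of 0.050 and a spot noise correlation of 0.47. It lies below 0.51, a value of 2 arrays in 1 scan, but above 0.4, the highest between groups in different scans. So 1 array measured again stays open, as does 1 RNA on 2 arrays, which was not tested. A biological closeness of separate rats was not tested.

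Proximal tubule markers were lower after RYGB in diabetic rats, in a list call that did not pass with an estimated correlation. A smaller share of proximal tubule alone would lower them alike, but their changes had an interquartile range of 1.74 (quartiles -1.7 and 0.04, median SE 0.24). This range cannot exclude a smaller share joined by changes of single genes, which stays open. The distal convoluted tubule list shifted up in the same comparison. The median of the proximal tubule markers stayed at -1.25 with quantile scaling, which argues against the scaling. Relative to all genes it stayed at -1.27 without DM+RYGB 2, which argues against dilution by heart RNA. A change of gene activity within the tubule may remain as a hypothesis, as may a loss of some tubule segments, which was not tested.

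For diabetes in sham rats, limma on the 6 arrays as separate samples called 9768 genes for the real split and 0 for the highest other split (12150 and 2128 at an unadjusted p under 0.05), and for RYGB in control rats 13028 and 0 (15104 and 1258). In each case 1 of 10 splits, the real one, reached that count, and 10 splits are too few for a share under 0.05.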

How the results depend on the processing

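The block of scan day, the fit of all 11 arrays as separate samples and the leaving out of both arrays of a pair were chosen after the data had been seen, the other tests before. Of 278 named changes of genes, 108 kept their direction and their side of the threshold under every alternative, and over 7162 values 6668 did, 458 missed the threshold, 28 newly passed it and 8 reversed. Of the 98 named list shifts 2 kept theirs throughout, and over all alternatives they did in 2115 of 2352 values, with 229 no longer past the threshold, 7 newly past it and 1 reversed. Among the 98, 16 were no longer past it with quantile scaling, 16 with the deposited table and 2 with median scaling, so some list calls depend on the scaling. With normexp, Camkk2 in DM+RYGB against Control+Sham became 0.95, Mmp20 and Senp17 after RYGB in diabetic rats 0.79 and 0.65, and Kprp, Senp17 and Vom1r82 in the interaction 0.24, 0.89 and 1.46, all short of the threshold. Leaving out arrays, Prkaa2 ran from -0.36 (without DM+RYGB 2) to 0.61 (without DM+RYGB 1) for RYGB in diabetic rats (adjusted p 0.025 and 0.0059) and from -0.48 to 0.49 in the interaction (0.03 and 0.031), so each passed, in opposite directions. The AMPK list for RYGB in diabetic rats, with a median shift of -0.45, passed upward in fry. The shift is relative to all genes, whose median change was 0.57 here, and fry makes no such reference, so the 2 directions answer different questions. The causes of the reversals of genes were not tested.

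The counts below are for diabetes in sham rats, RYGB in diabetic rats, RYGB in control rats, diabetes in RYGB rats, DM+RYGB against Control+Sham and the interaction, in this order. Normexp gave 186, 5409, 105, 3245, 7080 and 1124 genes, where the median residual spread was 0.45 beside 0.22. A 2-fold threshold with an adjusted p gave 1610, 7917, 3579, 3398, 8828 and 3670, fewer by construction, and with an unadjusted p 2144, 8588, 3923 and 9172 for all but RYGB in control rats and the interaction. Array weights gave 9135, 7217, 16104 and 4897 in the first 4. With only the groups compared, 6221 genes passed for RYGB in diabetic rats and 1692 for diabetes in RYGB rats. All 11 arrays as separate samples gave 8265 for diabetes in sham rats, 11716 for RYGB in control rats and 9517 for the interaction. With scan day as a block, which left 2 residual degrees of freedom, limma gave 284, 4937, 0, 3182, 0 and 93, and 5745, 11167, 4185, 9083, 8504 and 7190 at an unadjusted p under 0.05. The replicate block, tried because groups share replicate numbers, gave 3434, 13821, 7337, 7852, 14551 and 4782. Of 12 pairs with the same number 5 correlated above 0.1, with a range of -0.36 to 0.45. In groups of 2 samples the deviations mirror each other and some of these values repeat, so they cannot decide on pairing. The numbers were not taken as pairs.

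Leaving out an array or a pair counted as 1 sample gave 1264 to 7355, 7873 to 13736, 742 to 9874, 3554 to 9548, 12080 to 15311 and 2321 to 8394 genes. Where this leaves 1 sample in a group, that sample is assumed to vary like the other groups. The count for diabetes in sham rats was 1844 without Control+Sham 1, 2031 without Control+Sham 2, 2302 without DM+Sham 1, 1264 without DM+Sham 2 and 3, 2634 without Control+RYGB 1 or without Control+RYGB 2 and 3, and 7355 without either DM+RYGB array. For RYGB in diabetic rats it was 7873 without DM+Sham 2 and 3. For RYGB in control rats it was 2107 without Control+Sham 1, 2542 without Control+Sham 2, 742 without Control+RYGB 1 and 965 without Control+RYGB 2 and 3, and for diabetes in RYGB rats 3712 and 3554 without these same samples of Control+RYGB. For the interaction it was 3297 without Control+Sham 1, 2876 without DM+Sham 2 and 3, 2658 without Control+RYGB 1, 2321 without Control+RYGB 2 and 3 and 8394 without DM+RYGB 2.

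The opposition of diabetes and RYGB, -0.24, kept its sign in each alternative for which it was computed, which leaves out robust and weighted fits, single probes and fits of only the groups compared. It was -0.04 with normexp, -0.17 with quantile scaling, -0.13 with the deposited table, -0.16 with probes above background on all arrays, -0.33 with 11 separate arrays, -0.39 with scan day as a block and -0.17 with the RYGB change read against DM+Sham 2 and 3. Leaving out arrays gave -0.44 (without DM+Sham 1) to -0.15 (without DM+Sham 2 and 3). The count of called lists, 92, ran from 86 to 123 under other settings, except for 0 with an estimated correlation, where 25 had an unadjusted p under 0.05, and 149 in fry. The share of probes well above background, 77.7% to 93.5%, was lowest in Control+Sham 2 and Control+Sham 1 (80.2%) and limits what can be said of dim genes there, while Control+Sham 3 reached 90.5%.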

Other observations

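The added lists for urothelium, liver and heart were chosen after the values had been seen, and so were the tests on them.

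Genes of the urothelium, the lining of the renal pelvis and bladder, were lower than in Control+Sham in each of the other 3 groups, in comparisons that share the Control+Sham samples. With an estimated correlation none of these calls nor that of the interaction passed (adjusted p = 0.49 for each). Of 14 measured genes, 8 fell with diabetes in sham rats (shift -2.79, adjusted p 2.5e-08), with Upk1a at -2.72, Upk1b at -2.81 and Upk3a at -4.27. After RYGB in control rats 8 fell and 1 rose (shift -3.33, adjusted p 1.5e-09), with Upk1b at -3.45 and Upk3a at -3.55, and in DM+RYGB against Control+Sham 9 fell and 2 rose (-2.47, adjusted p 7.5e-07). In the interaction 10 of 14 were positive (3.71, adjusted p 2.6e-06). The shifts were 0.79 for RYGB in diabetic rats (adjusted p 0.22) and 0.13 for diabetes in RYGB rats (adjusted p 0.31). With genes below background at their bound the first 3 medians stayed at -2.79, -3.33 and -2.47, and the keratins Krt7 and Krt19 did not pass with diabetes in sham rats (-0.21 and -0.73).

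Genes best known from the liver rose in 13 of 20 cases and fell in 1 after RYGB in control rats (shift 1.33, adjusted p 9.2e-05). None of the liver calls passed with an estimated correlation (adjusted p = 0.49 to 0.79). Albumin, Alb, stood at 2.95, Apoa2 at 3.01 and haptoglobin, Hp, at 2.27, against the male-specific Cyp2c11 at -2.82. In diabetic against control RYGB rats 15 of 20 fell and none rose (-2.01, adjusted p 7.3e-13), with Alb at -2.72, Serpinc1 at -4.64 and Fga at -3.82. In diabetic sham rats 6 fell and 2 rose (-0.47, adjusted p 0.022), with Cyp2c11 at -5.98 and Alb at -3.15. The interaction was -1.23 (adjusted p 1.6e-05), and RYGB in diabetic rats, with 4 higher and 5 lower, had an adjusted p of 1.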
